A study of Mus musculus with 41 samples.

How the data were processed

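RNA from 41 mouse spleens (C57BL/6 strain per the labels) was measured on 41 Affymetrix MOE430A arrays, 1 array per spleen and nothing pooled. Spleens were taken 6 h after cecal ligation and puncture (CLP, an operation that releases gut bacteria into the abdomen), sham laparotomy, tracheal instillation of Pseudomonas, or tracheal instillation of saline, in wild-type mice (WT) and in mice overexpressing bcl-2 (BCL2). The 8 groups held 5 arrays each, except WT_CLP with 6. The series' design text states 6 wild-type sham mice, and 5 arrays carry that label. Arrays of 1 group are taken as different animals, as the labels number them. Each sample title ends in a number whose meaning is not given in the sources used here; arrays that share it are taken as 1 batch, and every fit with batch rests on this reading. Batches pneumonia_A and pneumonia_B held 3 and 2 arrays of each of the 4 pneumonia-model groups. Batch surgery_A held 5 WT_CLP and 4 WT_sham arrays, and surgery_B held all 10 arrays of BCL2 surgery mice with 1 WT_CLP and 1 WT_sham array (WT_CLP 1 and WT_sham 1). The word star stands in the labels of 3 arrays (WT_CLP 5, WT_CLP 6 and WT_sham 3), with a meaning not given in the sources used here.

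The table deposited by the authors gives 1 linear intensity per probe set and array, with no negative values and with 1 to 10 zeros per array. Array medians lay between 298 and 344 (298.3 to 343.7 before rounding), so the arrays had been brought to a common scale; the scaling or normalization method is not given in the sources used here. No image or cell-level files were used here. Arrays have no counting depth: their number and their signal over background limit the precision. The deposited values were floored at the 20th percentile of all values (124.0, which took in 17.5 to 22.2% of an array's probe sets) and then transformed to log2. Of 22690 probe sets, 64 controls were left out. The probe table paired 20380 with 1 symbol and 691 with several, and 1555 had no symbol there. A probe set was kept if it lay above its array's 40th percentile in at least 5 of the 41 arrays, which 15055 did. Each gene with 1 symbol was represented by its probe set with the highest mean over all arrays, giving 9164 genes. No 2 arrays were identical.

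Differences were fitted with limma (version 3.58.1 in R 4.3.3; lmFit, then eBayes with trend and robust options). The pneumonia model (20 arrays) and the surgery model (21 arrays) were fitted apart, each with 4 group means and batch as an additive term. The contrasts between the CLP and the pneumonia response came from 1 fit over all 41 arrays. A gene was called when its Benjamini-Hochberg adjusted p, over the 9164 genes of a contrast, was under 0.05; all tests were two-sided. A gene written as rising, falling or differing passed this threshold unless its adjusted p says otherwise. Errors after ± are standard errors of the limma estimate unless SD or another source is stated. Where every array of a control group lay at the floor, the fold change is a lower bound, written "at least". In all, 12 contrasts were tested: 4 infection responses, 2 interactions of genotype with infection, 4 genotype differences and 2 differences between the responses.

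Shifts of 25 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 25 lists of a contrast. Camera with an estimated correlation and fry were alternatives. The lists were inflammatory cytokines and chemokines, acute phase and cytokine-feedback, NF-kB target and feedback, interferon-stimulated, pro-apoptotic and caspase, anti-apoptotic, glucocorticoid-responsive, immediate-early, heat shock and chaperone, oxidative phosphorylation, MHC class II antigen presentation and cell cycle genes, markers of B cells, T cells, NK and cytotoxic cells, neutrophils, monocytes and macrophages, dendritic cells, erythroid cells, platelets and megakaryocytes, plasma cells, pancreas, adipose tissue, and stroma and endothelium, and sex-linked transcripts. A few genes stand in more than 1 list, at most 2 per pair of lists. For each contrast the named genes are the 6 called genes with the most positive and the 6 with the most negative change, up to 4 members of each list with the smallest p (and its other called members if 6 or fewer), and Bcl2 always. The design, the lists, this rule and most alternatives were fixed before the data were examined. The alternatives that leave out or adjust for arrays with pancreas transcripts, adjust for the erythroid list, leave out single arrays for the neutrophil list, or hold out the WT arrays of surgery_B were chosen after seeing the data.

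The procedure was tested on simulated data of the same design, with 9164 genes of which 100 per contrast were changed by 1 and 100 by 0.5 log2 units. It recovered 94 to 100% of the former and 51 to 92% of the latter, and 1.54 to 6.77% of the calls were false. For the pneumonia response in WT mice, the T cell list was shifted by 0.5 log2 units: camera called it and 0 of the other lists. The simulated genes vary independently of each other, with no batch difference, no floor and no factor shared by the genes of an array. So this test does not cover correlation between the genes of a list, nor false calls that such shared factors would give. Alternatives covered quantile normalization, median centring, other floors and filters, every probe set on its own, the batch term, each batch alone, other fits and weights, and leaving out each array in turn. Arrays of different groups that share an animal number in the sample titles had residual correlations of mixed sign. Pairs of unlike numbers were not compared, so pairing is not excluded, and no paired design was used.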

Results

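Gene expression was measured on 41 mouse spleens, 6 h after the start of 2 kinds of sepsis. Wild-type mice (WT) and mice overexpressing bcl-2 (BCL2) received Pseudomonas or saline into the trachea, or cecal ligation and puncture (CLP) or a sham laparotomy. Each of the 8 groups held 5 spleens, apart from 6 in WT_CLP. Array medians lay between 298 and 344 intensity units, and the mean correlation of an array with its group was 0.948 to 0.986. The first 3 principal components held 26.3, 19.6 and 18.1% of the variance.

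Bcl2, the apoptosis inhibitor overexpressed in the BCL2 mice, had a signal of 361 to 525 on the 21 WT arrays and of 1311 to 1674 on the 20 BCL2 arrays, with no overlap. By group the BCL2 minus WT difference was 1.84 ± 0.07 log2 units in saline mice (3.58-fold), 1.60 ± 0.07 after Pseudomonas (3.03-fold), 1.82 ± 0.11 in sham mice (3.54-fold) and 1.89 ± 0.11 after CLP (3.71-fold). Pneumonia raised Bcl2 itself slightly in WT mice (0.27 ± 0.07, adjusted p = 0.00654, above every control array in 5 of 5). In the other 3 responses its change did not pass the test: 0.03 ± 0.07, adjusted p = 0.872 for pneumonia in BCL2 mice, -0.09 ± 0.07, adjusted p = 0.391 for CLP in WT mice and -0.02 ± 0.08, adjusted p = 0.912 for CLP in BCL2 mice. The labels do not say which part of the transcript the transgene carries, so whether this 1 probe set reads the transgene is not known.

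**Figure D1:**
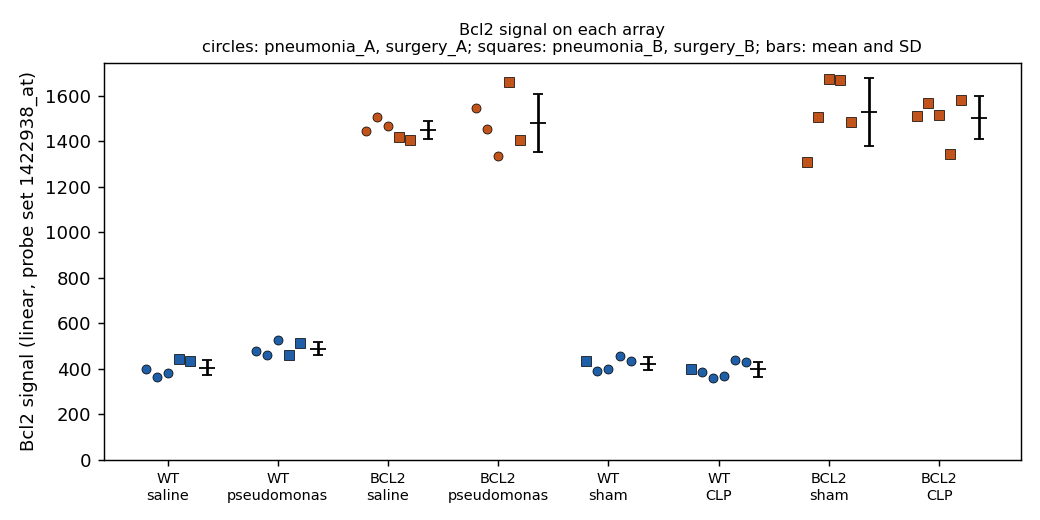
Linear signal of the Bcl2 probe set on each of the 41 arrays by group, with group means and SD; the lowest BCL2 array lies at 1311 and the highest WT array at 525. Circles are batches pneumonia_A and surgery_A, squares are pneumonia_B and surgery_B.

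In the spleens of WT mice with pneumonia Cxcl2, a chemokine that attracts neutrophils, was at least 25.8-fold higher (4.69 ± 0.20, adjusted p = 4.78e-13, above every control array in 5 of 5), with all 5 saline arrays at the floor. Cxcl1, a chemokine of the same family, rose 17.3-fold (4.11 ± 0.39, adjusted p = 4.64e-07, above every control array in 5 of 5). The metallothioneins Mt2 and Mt1, which bind zinc and copper, rose 15.3-fold (3.93 ± 0.09, adjusted p = 1.04e-17, above every control array in 5 of 5) and 8.49-fold (3.09 ± 0.09). Cd14, the lipopolysaccharide co-receptor, rose 7.42-fold (2.89 ± 0.13), and the cytokine Il6 was at least 5.65-fold higher (2.50 ± 0.28). The strongest decreases were in Slfn4 (-1.73 ± 0.14, adjusted p = 7.23e-09, below every control array in 5 of 5), the transcription factor Tcf21 (-1.64 ± 0.20), Tardbp (-1.58 ± 0.13), Wfdc21 (-1.52 ± 0.12), Gm20559 (-1.42 ± 0.11) and Ccr2 (-1.40 ± 0.09), the receptor by which monocytes follow Ccl2. In both genotypes another probe set of Tardbp rose, so the direction of that gene depends on the probe set.

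Inflammatory lists moved upward together in these mice. Of the inflammatory cytokines and chemokines, 10 of 21 rose and 0 fell, or 12 and 0 adjusted over the list alone; besides the above, Cxcl10 (1.47 ± 0.17), Csf3 (1.28 ± 0.09), Il1a (1.15 ± 0.11) and the anti-inflammatory Il10 (1.01 ± 0.09) were among them. Cytokines and chemokines as a list had adjusted p = 4.97e-09, and adjusted p = 0.0148 with an estimated correlation. Among NF-kB target and feedback genes, 14 of 19 rose and 1 fell, or 15 and 1 adjusted over the list alone, with Nfkbiz (1.62 ± 0.13), the feedback inhibitors Tnfaip3 (1.16 ± 0.12) and Tnip1 (1.12 ± 0.08), and Ier3 (0.86 ± 0.09). NF-kB targets as a list had adjusted p = 2.66e-11, and adjusted p = 0.000893 with an estimated correlation. Acute phase and cytokine-feedback genes went both ways: 10 of 21 rose and 4 fell, or 11 and 5 adjusted over the list alone, with Socs3, an inhibitor of cytokine signalling, up by 1.24 ± 0.07 and haptoglobin (Hp) at -1.28 ± 0.10. Acute phase genes as a list had adjusted p = 0.00272, and adjusted p = 0.298 with an estimated correlation. For glucocorticoid-responsive genes, 15 of 20 rose and 0 fell, or 16 and 0 adjusted over the list alone, including the phosphatase Dusp1 (1.81 ± 0.18). Glucocorticoid-responsive genes as a list had adjusted p = 3.51e-17, and adjusted p = 0.0104 with an estimated correlation. Immediate-early genes followed, as 13 of 19 rose and 0 fell; Junb changed by 1.03 ± 0.11 and Dusp2 by 1.40 ± 0.09. Immediate-early genes as a list had adjusted p = 1.87e-11, and adjusted p = 0.0148 with an estimated correlation.

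Interferon-stimulated genes moved the other way in WT pneumonia: 0 of 28 rose and 9 fell, or 0 and 11 adjusted over the list alone, among them Usp18 (-0.69 ± 0.09), Oasl2 (-0.91 ± 0.12) and the proteasome subunit Psmb9 (-0.38 ± 0.09). Interferon-stimulated genes as a list had adjusted p = 0.00267, and adjusted p = 0.298 with an estimated correlation. Within the anti-apoptotic list 5 of 13 rose and 1 fell; Birc2 (0.90 ± 0.08) and Birc3 (0.91 ± 0.10) rose and Xiap (-0.45 ± 0.08) fell. Anti-apoptotic genes as a list had adjusted p = 0.00761, and adjusted p = 0.0622 with an estimated correlation. Pro-apoptotic and caspase genes were split: 6 of 23 rose and 6 fell, or 8 and 6 adjusted over the list alone, with Bcl2l11 (0.83 ± 0.11), whose product Bim opposes Bcl2, Fas (0.52 ± 0.08) and Apaf1 (0.67 ± 0.12) up and Aifm1 (-0.35 ± 0.07) down. Pro-apoptotic genes as a list did not pass (adjusted p = 0.473). Heat shock and chaperone genes had no common direction (2 of 15 rose and 5 fell, or 2 and 7 adjusted over the list alone), with Hspb1 at 1.33 ± 0.15 and Dnajb1 at -0.50 ± 0.10. Heat shock genes as a list did not pass (adjusted p = 0.203). Oxidative phosphorylation (0 of 27 rose and 3 fell, or 0 and 1 adjusted over the list alone) and MHC class II genes (1 of 12 rose and 0 fell) had few called members. Oxidative phosphorylation genes as a list did not pass (adjusted p = 0.337). MHC class II genes as a list did not pass (adjusted p = 0.235). The cell cycle list had a small shift upward (median 0.20; list adjusted p = 0.0238, and adjusted p = 0.767 with an estimated correlation) with Cdt1 (0.71 ± 0.11) as its single called member.

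Markers of cell types were tested as lists too. B cell markers shifted down, and 0 of 14 rose and 4 fell, or 0 and 5 adjusted over the list alone: the homing receptor Cxcr5 (-0.80 ± 0.10), Ms4a1 (-0.71 ± 0.10), which encodes CD20, and complement receptor Cr2 (-0.48 ± 0.08). B cell markers as a list had adjusted p = 0.0238, and adjusted p = 0.546 with an estimated correlation. Among T cell markers 1 of 18 rose and 3 fell, with Cd5 at -0.59 ± 0.09 and Ccr7 at 0.52 ± 0.12. T cell markers as a list did not pass (adjusted p = 0.276). For neutrophil markers 2 of 17 rose and 7 fell, or 3 and 7 adjusted over the list alone; S100a8 (-1.10 ± 0.10), S100a9 (-1.20 ± 0.11) and Mmp8 (-1.30 ± 0.14) fell while Ngp (0.71 ± 0.17) rose. Neutrophil markers as a list did not pass (adjusted p = 0.057). Of the monocyte and macrophage markers 2 of 18 rose and 6 fell, including the iron exporter Slc40a1 (-0.95 ± 0.15). Monocyte and macrophage markers as a list did not pass (adjusted p = 0.057). The other lists were as follows: NK and cytotoxic cells, 1 of 10 rose and 3 fell; dendritic cells, 1 of 13 rose and 2 fell, with Cd83 at 1.25 ± 0.09; plasma cells, 1 of 7 rose and 1 fell; stroma and endothelium, 2 of 15 rose and 2 fell. NK and cytotoxic markers as a list did not pass (adjusted p = 0.493). Dendritic cell markers as a list did not pass (adjusted p = 0.775). Plasma cell markers as a list did not pass (adjusted p = 0.695). Stromal markers as a list did not pass (adjusted p = 0.706). Platelet and megakaryocyte markers (2 of 11 rose and 0 fell) and adipose markers (2 of 7 rose and 0 fell) shifted upward, with Thbs1 at 0.67 ± 0.13 and Scd1 at 0.59 ± 0.08. Platelet markers as a list had adjusted p = 0.0238, and adjusted p = 0.298 with an estimated correlation. Adipose markers as a list had adjusted p = 0.0238, and adjusted p = 0.0789 with an estimated correlation. Erythroid markers shifted upward as a list with no called member (median 0.28; list adjusted p = 0.0424, and adjusted p = 0.767 with an estimated correlation), and neither pancreas markers (list adjusted p = 0.435) nor sex-linked transcripts (list adjusted p = 0.695) passed the test.

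In all, 1818 of 9164 genes were called in WT pneumonia (limma, n = 5 and 5), 669 up and 1149 down, and 93 of them changed at least 2-fold. Within 1 batch the count was 1037 in pneumonia_A (3 arrays a group) and 260 in pneumonia_B (2 arrays a group). Camera called 12 of 25 lists at the preset correlation, and 4 of those also with an estimated one: cytokines, NF-kB, glucocorticoid-responsive and immediate-early genes.

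The spleens of BCL2 mice answered pneumonia with many of the same genes. Cxcl2 was at least 15.5-fold higher (3.95 ± 0.20, adjusted p = 1.06e-11, above every control array in 5 of 5), and Cxcl1 (3.58 ± 0.39), Mt2 (3.20 ± 0.09), Cd14 (2.83 ± 0.13), Mt1 (2.72 ± 0.09) and Il6 (at least 2.02 ± 0.28, its saline arrays being at the floor) rose. Tcf21 (-1.65 ± 0.20), Tardbp (-1.41 ± 0.13), Chac2 (-1.34 ± 0.14), Gm20559 (-1.31 ± 0.11), Dynll1 (-1.30 ± 0.09) and Crebzf (-1.30 ± 0.07) fell most. The cytokine list (8 of 21 rose and 0 fell) held Il10 (1.04 ± 0.09), Cxcl10 (1.70 ± 0.17) and Csf3 (0.74 ± 0.09). Cytokines and chemokines together had adjusted p = 3.67e-09, and adjusted p = 0.0147 with an estimated correlation. NF-kB targets (12 of 19 rose and 1 fell, or 13 and 1 adjusted over the list alone), glucocorticoid-responsive genes (14 of 20 rose and 0 fell) and immediate-early genes (11 of 19 rose and 1 fell, or 12 and 1 adjusted over the list alone) shifted upward, with Nfkbiz at 1.61 ± 0.13, Dusp1 at 1.77 ± 0.18 and Jun at 1.08 ± 0.12. NF-kB targets together had adjusted p = 1.32e-10, and adjusted p = 0.00127 with an estimated correlation. Glucocorticoid-responsive genes together had adjusted p = 2.79e-20, and adjusted p = 0.00499 with an estimated correlation. Immediate-early genes together had adjusted p = 7.95e-11, and adjusted p = 0.0184 with an estimated correlation. Acute phase genes did so too (10 of 21 rose and 3 fell, or 10 and 4 adjusted over the list alone), with Cebpb at 1.47 ± 0.19. Acute phase genes together had adjusted p = 7.4e-06, and adjusted p = 0.119 with an estimated correlation. B cell markers shifted down (0 of 14 rose and 7 fell, or 0 and 9 adjusted over the list alone), with Ms4a1 at -0.92 ± 0.10, and so did T cell markers (0 of 18 rose and 6 fell, or 0 and 7 adjusted over the list alone), with Cd5 at -0.67 ± 0.09. B cell markers together had adjusted p = 7.48e-05, and adjusted p = 0.172 with an estimated correlation. T cell markers as a list had adjusted p = 0.0467, and adjusted p = 0.552 with an estimated correlation.

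In BCL2 pneumonia 1581 genes were called (limma, n = 5 and 5), 435 up and 1146 down, and 57 changed at least 2-fold. The count was 935 in pneumonia_A alone and 124 in pneumonia_B alone. Of the genes called in WT and in BCL2 pneumonia, 380 rose in both against 31.8 expected by chance, 859 fell in both against 144 expected, and 0 went opposite ways. Camera called 9 lists at the preset correlation and 4 of them also with an estimated one (cytokines, NF-kB, glucocorticoid-responsive and immediate-early genes).

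The test of the difference between the genotypes' pneumonia responses called 3 genes (limma; 260 at an unadjusted p under 0.05). Mt2 rose less in BCL2 mice (difference -0.73 ± 0.13, adjusted p = 0.047), the change of Wfdc21 was less negative (0.99 ± 0.17, adjusted p = 0.047), and that of Chac2, a glutathione-degrading enzyme, more negative (-1.12 ± 0.20, adjusted p = 0.047). All 5 WT_pseudomonas arrays lay at the floor for Chac2, so its change in WT mice may be more negative than fitted. Neither the size nor the direction of its difference is settled. Lists of neutrophil markers (list adjusted p = 0.000222, and adjusted p = 0.493 with an estimated correlation), NF-kB targets (list adjusted p = 0.00803, and adjusted p = 0.436 with an estimated correlation), glucocorticoid-responsive genes (list adjusted p = 0.0173, and adjusted p = 0.527 with an estimated correlation) and erythroid markers (list adjusted p = 0.00544, and adjusted p = 0.591 with an estimated correlation) were among 9 called at the preset correlation, and 0 were called with an estimated one. The 3 calls are fragile: without the batch term, with plain eBayes or with median centring, limma called 0 (181, 259 and 210 at an unadjusted p under 0.05).

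**Figure D2:**
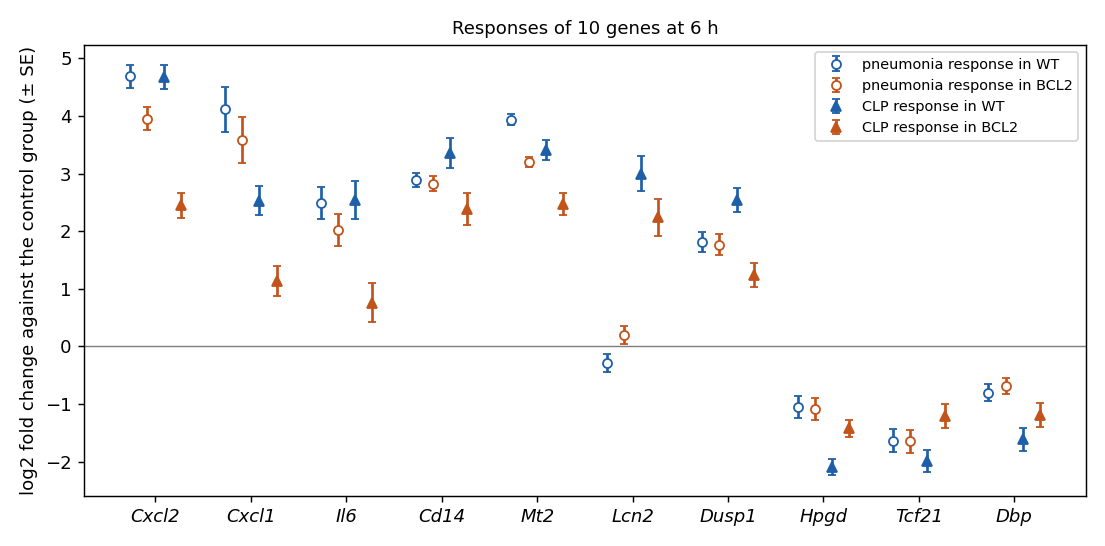
Change in log2 signal against the control group, with standard errors, of 10 genes in the 4 responses; Cxcl2 is at least 4.69 and 3.95 in pneumonia and at least 4.68 and 2.46 after CLP, in WT and BCL2 mice, since for Cxcl2 and Il6 all control arrays lie at the floor and the changes shown are lower bounds. Circles are pneumonia and triangles are CLP.

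CLP in WT mice raised Cxcl2 at least 25.6-fold (4.68 ± 0.21, adjusted p = 3.02e-11, above every control array in 6 of 6), again with all 5 control arrays at the floor. Mt2 (10.6-fold; 3.41 ± 0.18), Cd14 (10.2-fold; 3.36 ± 0.26), Mt1 (8.67-fold; 3.12 ± 0.17), the iron-sequestering protein Lcn2 (8.01-fold; 3.00 ± 0.30, adjusted p = 7.16e-07, above every control array in 6 of 6) and Dusp1 (5.85-fold; 2.55 ± 0.21) followed. Slc40a1, the cellular iron exporter ferroportin, fell most (-2.43 ± 0.23, adjusted p = 2.46e-07, below every control array in 6 of 6), then Hpgd (-2.09 ± 0.14), which degrades prostaglandins, Tcf21 (-1.99 ± 0.20), the potassium channel Kcnj10 (-1.94 ± 0.14), Cavin2 (-1.67 ± 0.16) and the circadian factor Dbp (-1.62 ± 0.20).

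All but 1 of the acute phase and cytokine-feedback genes rose after CLP in WT mice: 20 of 21 rose and 0 fell, or 21 and 0 adjusted over the list alone, with Timp1 (1.97 ± 0.13), Socs3 (1.25 ± 0.10) and Stat3 (1.07 ± 0.11). Acute phase genes by camera had adjusted p = 2.03e-22, and adjusted p = 0.0167 with an estimated correlation. Cytokines and chemokines (14 of 21 rose and 0 fell, or 15 and 0 adjusted over the list alone) included Cxcl1 (2.53 ± 0.25), Ccl3 (1.75 ± 0.18) and Csf3 (1.08 ± 0.13). Cytokines and chemokines by camera had adjusted p = 3.06e-11, and adjusted p = 0.0456 with an estimated correlation. NF-kB targets (13 of 19 rose and 0 fell, or 14 and 0 adjusted over the list alone) included the mitochondrial superoxide dismutase Sod2 (1.57 ± 0.14) and Bcl3 (1.10 ± 0.11). NF-kB targets by camera had adjusted p = 1.25e-10, and adjusted p = 0.0456 with an estimated correlation. Glucocorticoid-responsive genes (17 of 20 rose and 0 fell) included Fkbp5 (1.37 ± 0.09), and immediate-early genes (12 of 19 rose and 0 fell, or 14 and 1 adjusted over the list alone) Jun (1.38 ± 0.18) and Junb (1.10 ± 0.12). Glucocorticoid-responsive genes by camera had adjusted p = 6.68e-20, and adjusted p = 0.00267 with an estimated correlation. Immediate-early genes by camera had adjusted p = 4.88e-08, and adjusted p = 0.113 with an estimated correlation. The interferon-stimulated list shifted upward (8 of 28 rose and 3 fell, or 11 and 3 adjusted over the list alone) although Psmb9 (-0.58 ± 0.09), Psmb8 (-0.45 ± 0.10) and Bst2 (-0.38 ± 0.07) fell. Interferon-stimulated genes together had adjusted p = 0.00416, and adjusted p = 0.661 with an estimated correlation. Anti-apoptotic genes shifted upward (4 of 13 rose and 1 fell), with Birc3 at 0.87 ± 0.10, while in the pro-apoptotic list (6 of 23 rose and 3 fell) Bcl2l11 (1.32 ± 0.14), Pmaip1 (0.82 ± 0.11), which encodes the Bcl2 antagonist Noxa, and Casp4 (0.95 ± 0.08) rose. Anti-apoptotic genes together had adjusted p = 0.0112, and adjusted p = 0.0713 with an estimated correlation. Pro-apoptotic genes as a list did not pass (adjusted p = 0.117).

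Lymphocyte markers fell in the same spleens. Of the T cell markers 1 of 18 rose and 14 fell, or 2 and 14 adjusted over the list alone: Cd5 (-1.23 ± 0.12), Cd3g (-1.11 ± 0.14) and Thy1 (-0.67 ± 0.08) fell, and Ccr7 (1.23 ± 0.14) rose. T cell markers together had adjusted p = 0.000207, and adjusted p = 0.238 with an estimated correlation. Of the B cell markers 0 of 14 rose and 7 fell, or 0 and 8 adjusted over the list alone, with Fcer2a (-1.27 ± 0.12), Cd79b (-0.89 ± 0.15), Cr2 (-0.86 ± 0.13) and Ms4a1 (-0.84 ± 0.15). B cell markers by camera had adjusted p = 0.000802, and adjusted p = 0.238 with an estimated correlation. Neutrophil markers shifted upward (5 of 17 rose and 0 fell), with Mmp8 (1.29 ± 0.26), S100a8 (1.12 ± 0.35) and S100a9 (1.15 ± 0.36), and oxidative phosphorylation genes downward (0 of 27 rose and 9 fell), with Ndufa9 at -0.49 ± 0.08. Neutrophil markers as a list had adjusted p = 0.00627, and adjusted p = 0.661 with an estimated correlation. Oxidative phosphorylation genes as a list had adjusted p = 0.0298, and adjusted p = 0.661 with an estimated correlation. Without WT_CLP 4, whose neutrophil list mean was 10.87 (other WT_CLP arrays 9.17 to 9.95), the neutrophil list did not pass (adjusted p = 0.0977) and its mean change was 0.33 in place of 0.55. Monocyte and macrophage markers went both ways (3 of 18 rose and 9 fell, or 4 and 9 adjusted over the list alone): the scavenger receptor Marco rose (1.48 ± 0.26) and Ccr2 fell (-1.09 ± 0.13). Monocyte and macrophage markers as a list did not pass (adjusted p = 0.21). Gzmb, a granule protease of cytotoxic cells, rose by 1.90 ± 0.20 log2 units while the NK receptor subunit Klrd1 changed by -1.03 ± 0.14. Gzmb lay at the floor on 4 of 5 WT_sham arrays, so its rise may be larger. Pancreas transcripts were high on 2 of 5 WT_sham arrays and 1 of 6 WT_CLP arrays, and the pancreas list had a median difference of -1.11 between these groups (list adjusted p = 0.155).

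In WT mice 2736 genes were called after CLP (limma, n = 6 and 5), 956 up and 1780 down, and 144 changed at least 2-fold. In surgery_B alone, with 1 WT array in each arm and the spread taken from the BCL2 arrays, the count was 13. Camera called 11 lists at the preset correlation and 4 also with an estimated one: cytokines, acute phase, NF-kB and glucocorticoid-responsive genes.

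In BCL2 mice CLP raised Mt2 5.56-fold (2.47 ± 0.19, adjusted p = 5.35e-08, above every control array in 5 of 5), Cxcl2 at least 5.48-fold (2.46 ± 0.22), Cd14 5.22-fold (2.38 ± 0.27), Mt1 5.10-fold (2.35 ± 0.18), Ms4a6d 4.87-fold (2.28 ± 0.29) and Lcn2 4.73-fold (2.24 ± 0.32). Hpgd (-1.42 ± 0.15, adjusted p = 4.91e-06, below every control array in 5 of 5), the beta-glucan receptor Clec7a (-1.26 ± 0.17), Tcf21 (-1.21 ± 0.21), Dbp (-1.19 ± 0.20), Kazald1 (-1.03 ± 0.11) and Hs6st2 (-1.03 ± 0.13) fell most. Acute phase genes rose as a group (15 of 21 rose and 0 fell, or 17 and 0 adjusted over the list alone), with Timp1 at 1.32 ± 0.13 and Serpina3n at 1.02 ± 0.12. Acute phase genes as a list had adjusted p = 1.02e-24, and adjusted p = 0.00735 with an estimated correlation. So did cytokines (7 of 21 rose and 1 fell, or 8 and 1 adjusted over the list alone), with Ccl3 at 1.32 ± 0.19 and Il10 at 1.21 ± 0.14, NF-kB targets (9 of 19 rose and 0 fell, or 10 and 0 adjusted over the list alone), with Sod2 at 1.19 ± 0.15, and glucocorticoid-responsive genes (13 of 20 rose and 0 fell, or 15 and 0 adjusted over the list alone), with Zbtb16 at 1.61 ± 0.23 and Fkbp5 at 1.30 ± 0.10. Cytokines and chemokines as a list had adjusted p = 3.92e-10, and adjusted p = 0.0445 with an estimated correlation. NF-kB targets as a list had adjusted p = 6.3e-14, and adjusted p = 0.0156 with an estimated correlation. Glucocorticoid-responsive genes as a list had adjusted p = 1.36e-20, and adjusted p = 0.00223 with an estimated correlation. Anti-apoptotic genes (4 of 13 rose and 0 fell, or 5 and 0 adjusted over the list alone), with Pim1 at 0.78 ± 0.12, and heat shock and chaperone genes (4 of 15 rose and 0 fell, or 5 and 1 adjusted over the list alone), with the endoplasmic reticulum chaperones Hspa5 (0.34 ± 0.09) and Pdia4 (0.44 ± 0.09), shifted upward as well. Anti-apoptotic genes by camera had adjusted p = 6.51e-05, and adjusted p = 0.00735 with an estimated correlation. Heat shock genes as a list had adjusted p = 1.36e-05, and adjusted p = 0.0432 with an estimated correlation.

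Among cell markers after CLP in BCL2 mice, plasma cell markers shifted upward (3 of 7 rose and 0 fell, or 4 and 0 adjusted over the list alone), with Prdm1 (0.82 ± 0.14) and Xbp1 (0.55 ± 0.11), regulators of plasma cell differentiation. Plasma cell markers as a list had adjusted p = 0.000224, and adjusted p = 0.128 with an estimated correlation. Neutrophil markers did too (3 of 17 rose and 0 fell, or 5 and 0 adjusted over the list alone), with Mmp8 at 0.99 ± 0.27. Neutrophil markers together had adjusted p = 3.03e-07, and adjusted p = 0.29 with an estimated correlation. B cell markers (0 of 14 rose and 6 fell, or 0 and 7 adjusted over the list alone), with Fcer2a at -0.75 ± 0.13, and T cell markers (1 of 18 rose and 4 fell, or 1 and 6 adjusted over the list alone), with Cd5 at -0.65 ± 0.12, shifted down. B cell markers as a list had adjusted p = 0.0197, and adjusted p = 0.44 with an estimated correlation. T cell markers by camera had adjusted p = 0.0425, and adjusted p = 0.507 with an estimated correlation. Marco (2.09 ± 0.27) and the heme-degrading enzyme Hmox1 (0.83 ± 0.15) rose, and Slc40a1 (-0.88 ± 0.24) fell. The contrast called 907 genes (limma, n = 5 and 5, all in surgery_B), 342 up and 565 down, and 47 changed at least 2-fold; without BCL2_CLP 3 it called 544. Of 13 lists called at the preset correlation, 6 were also called with an estimated one: cytokines, acute phase, NF-kB, glucocorticoid-responsive, anti-apoptotic and heat shock genes. Genes called after CLP in both genotypes numbered 234 up in both against 35.7 expected by chance, 442 down in both against 110 expected, and 14 in opposite directions.

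The direct test of the difference between the genotypes' CLP responses called 314 genes (limma; 181 more positive and 133 more negative in BCL2 mice). It called 564 without WT_CLP 1 or WT_sham 1, and 179 to 209 without WT_sham 2, WT_sham 3, WT_CLP 5, WT_CLP 6 or BCL2_CLP 5. Of the chemokines and cytokines, Cxcl1 (difference -1.39 ± 0.36, adjusted p = 0.0397) and Csf3 (-0.89 ± 0.19) responded less in BCL2 mice. For Cxcl2 (-2.22 ± 0.30, adjusted p = 0.000944), Cxcl5 (-2.04 ± 0.40), Il6 (-1.78 ± 0.47, adjusted p = 0.0449) and Plscr1 (-1.46 ± 0.18) all sham arrays of both genotypes lay at the floor, so each response is a lower bound and these differences, which set the sham levels equal, are not exact. Gzmb (-1.54 ± 0.29), Rgs1 (-1.47 ± 0.30), Dusp1 (-1.31 ± 0.30), Mt2 (-0.94 ± 0.26) and the small heat shock protein Hspb1 (-1.03 ± 0.21) also had lower responses in BCL2 mice. Gzmb lay at the floor on 4 of 5 WT_sham and 3 of 5 BCL2_sham arrays, so its difference is not exact either. Immunoglobulin transcripts made up the most positive differences: Igkv4-72 (2.59 ± 0.29, adjusted p = 0.000274), Igk (2.55 ± 0.40; another probe set went the other way), Igkv4-68 (1.91 ± 0.39), Igkv6-14 (1.84 ± 0.29), Ighg3 (1.77 ± 0.43) and Igkv6-20 (1.75 ± 0.36). The change of Slc40a1, -0.88 ± 0.24 in BCL2 and -2.43 ± 0.23 in WT mice, differed by 1.54 ± 0.33. Of the genes of cell death, the responses of Bcl2l11 (-0.84 ± 0.20) and Pmaip1 (-0.67 ± 0.16) were lower in BCL2 mice and that of Aifm1 higher (0.48 ± 0.10).

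By list, 11 of 25 differed at the preset correlation and 0 with an estimated one. In cytokines 0 of 21 were higher and 5 were lower, or 0 and 8 adjusted over the list alone. Cytokines and chemokines together had adjusted p = 0.000435, and adjusted p = 0.374 with an estimated correlation. In acute phase genes 0 of 21 were higher and 2 were lower, or 0 and 11 adjusted over the list alone. Acute phase genes together had adjusted p = 1e-05, and adjusted p = 0.374 with an estimated correlation. In glucocorticoid-responsive genes 0 of 20 were higher and 2 were lower, or 0 and 4 adjusted over the list alone. Glucocorticoid-responsive genes together had adjusted p = 2.6e-06, and adjusted p = 0.271 with an estimated correlation. In immediate-early genes 0 of 19 were higher and 1 was lower, or 0 and 3 adjusted over the list alone. Immediate-early genes as a list had adjusted p = 1.15e-05, and adjusted p = 0.374 with an estimated correlation. More positive responses in BCL2 mice were seen for plasma cell markers (2 of 7 were higher and 0 were lower, or 4 and 0 adjusted over the list alone), with Jchain at 0.88 ± 0.22, for heat shock genes (2 of 15 were higher and 1 was lower, or 5 and 1 adjusted over the list alone), with Pdia4 at 0.98 ± 0.13 and Hsp90b1 at 0.71 ± 0.14, and for oxidative phosphorylation (1 of 27 was higher and 0 were lower), with Ndufa9 at 0.51 ± 0.11. Plasma cell markers together had adjusted p = 0.00187, and adjusted p = 0.374 with an estimated correlation. Heat shock genes together had adjusted p = 0.00379, and adjusted p = 0.374 with an estimated correlation. Oxidative phosphorylation genes together had adjusted p = 2.87e-05, and adjusted p = 0.374 with an estimated correlation. T cell markers (0 of 18 were higher and 1 was lower, or 5 and 1 adjusted over the list alone) shifted the same way, apart from Ccr7 at -1.09 ± 0.20, and so did monocyte and macrophage markers (2 of 18 were higher and 0 were lower), with C1qb at 0.80 ± 0.18. T cell markers as a list had adjusted p = 0.00125, and adjusted p = 0.374 with an estimated correlation. Monocyte and macrophage markers as a list had adjusted p = 0.00624, and adjusted p = 0.54 with an estimated correlation. The pancreas transcripts stood high on 3 of the 11 WT arrays and on 0 of the 10 BCL2 arrays of this test, and without the arrays that hold them 81 genes were called. Genotype and batch are nearly the same split here, with all BCL2 arrays and 1 WT array of each arm in surgery_B, so a batch difference in the response cannot be told apart from genotype. Within surgery_B limma called 0 genes (322 at an unadjusted p under 0.05), a test with 1 WT array in each arm.

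**Figure D3:**
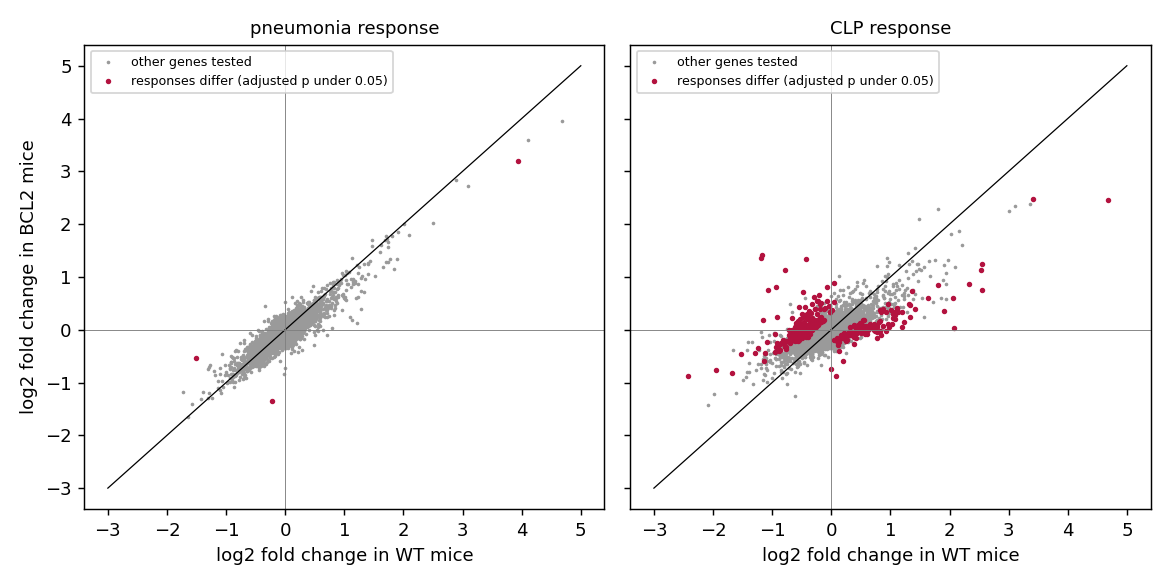
Change in log2 signal in WT mice (horizontal) against BCL2 mice (vertical) for 9164 genes, with the line of equality; genes whose responses differ at an adjusted p under 0.05 are red (3 in pneumonia, 314 after CLP). Across genes called in WT mice the slope is 0.830 in pneumonia and 0.483 after CLP; choosing the genes in WT mice by itself pulls both slopes below 1.

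The BCL2 spleens differed from WT spleens in mice without infection too. In saline mice the largest difference was at Mycn (8.88-fold; 3.15 ± 0.13, adjusted p = 3.11e-13, above every WT array in 5 of 5), on 1 of 3 probe sets. The other 2 Mycn probe sets differed by -0.21 and 0.027 and were not called. The one at 0.027 had mean signals of 122.2 in WT_saline and 129.1 in BCL2_saline mice, next to the floor of 124.0, so it says little about Mycn. Next came Hemgn (2.47 ± 0.53), the erythroid master regulator Klf1 (4.97-fold; 2.31 ± 0.31), Ermap (2.21 ± 0.35), Ctse (2.19 ± 0.36) and Rhd (2.14 ± 0.34), a blood group antigen. Wfdc21 (-1.41 ± 0.12), F13a1 (-1.40 ± 0.12), Mmp8 (-1.33 ± 0.14), Hp (-1.18 ± 0.10), Marco (-1.16 ± 0.15) and Cpe (-1.03 ± 0.15) were lowest. Of the erythroid markers 17 of 19 were higher and 0 were lower, or 18 and 0 adjusted over the list alone, with a median of 1.41 and Car1 (2.11 ± 0.23) and the transferrin receptor Tfrc (1.41 ± 0.21) among them. Erythroid markers as a list had adjusted p = 2.68e-23, and adjusted p = 0.0989 with an estimated correlation. Of the cell cycle genes 26 of 28 were higher and 0 were lower, or 27 and 0 adjusted over the list alone, with a median of 0.86, among them Cdc6 (1.51 ± 0.24) and Pcna (0.94 ± 0.16). Cell cycle genes as a list had adjusted p = 1.85e-26, and adjusted p = 0.0989 with an estimated correlation.

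Stromal and endothelial markers were lower in BCL2 saline mice (0 of 15 were higher and 9 were lower, or 0 and 13 adjusted over the list alone), as were acute phase genes (0 of 21 were higher and 9 were lower, or 1 and 12 adjusted over the list alone), neutrophil markers (0 of 17 were higher and 8 were lower) and dendritic cell markers (0 of 13 were higher and 4 were lower). Stromal markers as a list had adjusted p = 4.48e-08, and adjusted p = 0.0245 with an estimated correlation. Acute phase genes by camera had adjusted p = 1.36e-06, and adjusted p = 0.0989 with an estimated correlation. Neutrophil markers by camera had adjusted p = 0.000602, and adjusted p = 0.365 with an estimated correlation. Dendritic cell markers as a list had adjusted p = 0.0115, and adjusted p = 0.0989 with an estimated correlation. Sparc (-0.60 ± 0.11), Col4a1 (-0.71 ± 0.14), Lcn2 (-0.87 ± 0.16), S100a8 (-0.94 ± 0.10) and Itgax (-0.62 ± 0.10) are examples. Interferon-stimulated genes were higher as a list (5 of 28 were higher and 1 was lower), with Rsad2 at 1.44 ± 0.33 and Isg20 at 1.42 ± 0.27. Interferon-stimulated genes by camera had adjusted p = 0.0403, and adjusted p = 0.603 with an estimated correlation. The test called 1096 genes (limma, n = 5 and 5), 484 higher and 612 lower, with 82 at least 2-fold. Within 1 batch it called 512 in pneumonia_A and 3 in pneumonia_B, and the erythroid median was 1.65 and 1.05 there. Pancreas transcripts were high on 1 of the 5 WT_saline arrays, and the list's median in this contrast was -0.20 (list adjusted p = 0.774).

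After Pseudomonas the genotypes differed at Mycn (2.89 ± 0.13, adjusted p = 1.77e-12, above every WT array in 5 of 5), Car1 (1.83 ± 0.23), Ces2g (1.69 ± 0.32), Mgst3 (1.67 ± 0.38), Hemgn (1.66 ± 0.53) and Igkv14-111 (1.64 ± 0.27), and in the other direction at Hspb1 (-1.25 ± 0.15), Dcn (-1.21 ± 0.14), Marco (-1.07 ± 0.15), Cpe (-1.02 ± 0.15), Pdgfra (-1.02 ± 0.14) and S100a4 (adjusted p = 3.35e-06). Cell cycle genes (25 of 28 were higher and 0 were lower, or 26 and 0 adjusted over the list alone) and erythroid markers (15 of 19 were higher and 0 were lower, or 17 and 0 adjusted over the list alone) were higher, with Ccnb2 at 1.52 ± 0.26 and Nfe2 at 1.10 ± 0.23. Cell cycle genes together had adjusted p = 2.12e-24, and adjusted p = 0.16 with an estimated correlation. Erythroid markers together had adjusted p = 3.11e-16, and adjusted p = 0.16 with an estimated correlation. Lower lists were stroma (0 of 15 were higher and 9 were lower, or 0 and 13 adjusted over the list alone), acute phase (0 of 21 were higher and 11 were lower, or 0 and 14 adjusted over the list alone), NF-kB targets (0 of 19 were higher and 9 were lower, or 0 and 13 adjusted over the list alone) and B cells (1 of 14 was higher and 6 were lower), with Traf1 at -0.50 ± 0.11 and Cr2 at -0.93 ± 0.08. Stromal markers together had adjusted p = 1.44e-05, and adjusted p = 0.0774 with an estimated correlation. Acute phase genes as a list had adjusted p = 0.000117, and adjusted p = 0.187 with an estimated correlation. NF-kB targets together had adjusted p = 0.00045, and adjusted p = 0.0774 with an estimated correlation. B cell markers together had adjusted p = 0.00296, and adjusted p = 0.295 with an estimated correlation. The count was 1614 (limma, n = 5 and 5; 566 higher, 1048 lower), 422 in pneumonia_A alone, 3 in pneumonia_B alone and 1043 without BCL2_pseudomonas 5. Between the saline and Pseudomonas contrasts 372 genes were higher in both and 461 lower in both, against 29.9 and 70.0 expected by chance, and 1 went opposite ways.

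Many of the same genes differed between the genotypes in the surgery model. In sham mice Mycn (3.02 ± 0.14, adjusted p = 8.52e-12, above every WT array in 5 of 5), Hemgn (2.27 ± 0.41), Ermap (2.22 ± 0.43), Rhd (2.20 ± 0.39), Icam4 (2.16 ± 0.43) and Tmcc2 (2.09 ± 0.36) were highest in BCL2 mice, and Car3 (-1.63 ± 0.32), Colec12 (-1.27 ± 0.18), Dcn (-1.23 ± 0.22), Cr2 (-1.20 ± 0.19), Dmpk (-1.18 ± 0.26) and Tcf21 (-1.18 ± 0.29) lowest in the fit with batch, whose term rests on WT_sham 1 and WT_CLP 1. The BCL2_sham and WT_sham means lay closer together than these fitted values for Hemgn (11.62 and 10.08), Ermap (11.26 and 9.58), Rhd (11.11 and 9.42), Icam4 (9.42 and 7.72) and Tmcc2 (12.08 and 10.45). Those of Tcf21 were 9.79 and 10.01, with 1 of 5 BCL2 arrays below every WT array, and with no batch term it was not called (-0.22, adjusted p = 0.661). Those of Colec12 were 7.26 and 7.90, with 2 of 5 arrays below. Car3 is a member of the adipose list, whose means were 9.44 to 9.93 on the WT arrays of surgery_A and 8.63 to 9.06 on all 12 arrays of surgery_B, so this tissue marker moves with batch. The Car3 group means were 7.45 in BCL2_sham and 10.29 in WT_sham, and 7.37 in BCL2_CLP and 10.02 in WT_CLP, which lie further apart than the fitted differences. Erythroid markers (16 of 19 were higher and 0 were lower, or 19 and 0 adjusted over the list alone) and cell cycle genes (23 of 28 were higher and 0 were lower, or 25 and 0 adjusted over the list alone) were higher, with Trim10 at 2.01 ± 0.35 and the proliferation marker Mki67 at 1.67 ± 0.33. Erythroid markers by camera had adjusted p = 9.78e-18, and adjusted p = 0.217 with an estimated correlation. Cell cycle genes by camera had adjusted p = 6.43e-16, and adjusted p = 0.395 with an estimated correlation. T cell markers were lower (0 of 18 were higher and 6 were lower, or 1 and 11 adjusted over the list alone), with Lat at -0.65 ± 0.15. T cell markers together had adjusted p = 0.0005, and adjusted p = 0.459 with an estimated correlation. The BCL2_sham and WT_sham means were 9.730 and 9.999 for Lat, 8.930 and 9.002 for Cd5 and 10.16 and 10.27 for Cd3g, with 3, 2 and 2 of 5 arrays below every WT array, so most of the fitted difference of these 3 comes from the batch term. The pancreas list had a median of -0.36 here (list adjusted p = 0.801). After CLP the genotypes differed most at Igk (3.17 ± 0.41), Igkv4-72 (2.97 ± 0.30, adjusted p = 1.68e-05, above every WT array in 5 of 5), Igkv6-14 (2.76 ± 0.29), Igkv6-20 (2.70 ± 0.37), Mycn (2.61 ± 0.14) and Hemgn (2.59 ± 0.41), and in the other direction at Cxcl2 (-1.80 ± 0.31), Hspb1 (-1.54 ± 0.21), Emp1 (-1.46 ± 0.34), Errfi1 (-1.42 ± 0.38), Car3 (-1.40 ± 0.32) and Cpe (-1.30 ± 0.26).

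Erythroid markers (16 of 19 were higher and 0 were lower, or 18 and 0 adjusted over the list alone) and cell cycle genes (24 of 28 were higher and 0 were lower, or 25 and 0 adjusted over the list alone) were also higher in BCL2 mice after CLP, with Klf1 at 2.50 ± 0.36 and Cdc6 at 2.02 ± 0.35. Erythroid markers as a list had adjusted p = 1.89e-19, and adjusted p = 0.155 with an estimated correlation. Cell cycle genes as a list had adjusted p = 1.33e-21, and adjusted p = 0.159 with an estimated correlation. Plasma cell markers were higher (4 of 7 were higher and 0 were lower), with Jchain at 1.15 ± 0.22, and glucocorticoid-responsive genes lower (0 of 20 were higher and 6 were lower, or 0 and 8 adjusted over the list alone), with Dusp1 at -1.12 ± 0.30. Plasma cell markers by camera had adjusted p = 0.000718, and adjusted p = 0.17 with an estimated correlation. Glucocorticoid-responsive genes by camera had adjusted p = 4.9e-05, and adjusted p = 0.159 with an estimated correlation. The test called 1055 genes in sham mice (506 higher, 549 lower; limma, n = 5 and 5) and 1241 after CLP (642 higher, 599 lower; limma, n = 5 and 6). With batch in the model these 2 contrasts rest on WT_sham 1 and WT_CLP 1; within surgery_B limma called 15 and 233 genes, and without WT_sham 1 or WT_CLP 1 it called 486 and 309. With no batch term it called 4081 after CLP, and with only the groups compared in the fit 8 in sham mice. Across the 2 models, 261 genes were higher and 233 lower in both saline and sham mice, against 26.7 and 36.7 expected by chance, and 0 differed in direction.

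**Figure D4:**
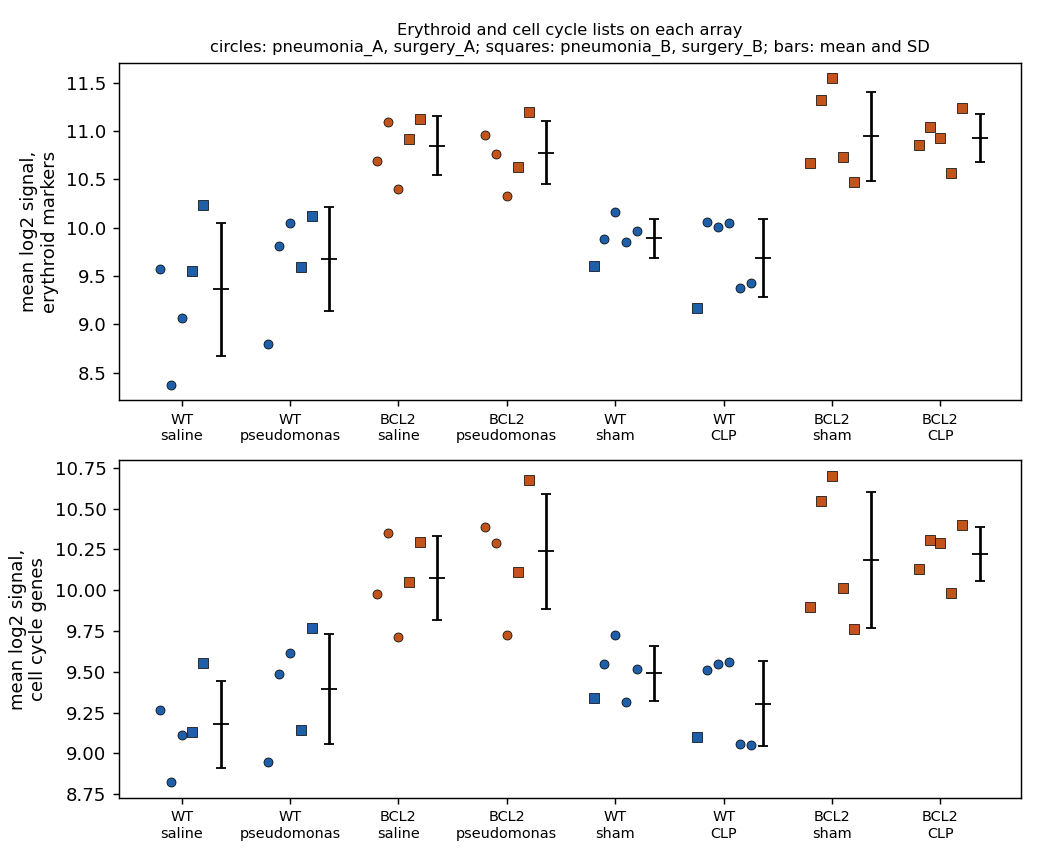
Mean log2 signal of the erythroid markers (top) and the cell cycle genes (bottom) on each array by group, with group means and SD. Erythroid group means are 9.36 in WT_saline and 10.85 in BCL2_saline, and cell cycle means 9.18 and 10.08.

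The 2 infections were compared within each genotype, each response taken against its own control. In WT mice Lcn2 (3.29 ± 0.37, adjusted p = 6.37e-07), Wfdc21 (2.90 ± 0.44), Slfn4 (2.84 ± 0.43), the formyl peptide receptor Fpr2 (2.73 ± 0.28), Mmp8 (2.59 ± 0.32) and Hp (2.57 ± 0.30) responded more positively to CLP. Slc40a1 (-1.48 ± 0.29), the vasodilator peptide Adm (-1.37 ± 0.30), Id3 (-1.31 ± 0.19), Cavin2 (-1.25 ± 0.22), Nrgn (-1.24 ± 0.17) and Vwf (-1.15 ± 0.18) responded more negatively. Acute phase genes (11 of 21 were higher and 0 were lower, or 15 and 0 adjusted over the list alone), interferon-stimulated genes (2 of 28 were higher and 0 were lower, or 18 and 0 adjusted over the list alone) and neutrophil markers (4 of 17 were higher and 0 were lower, or 7 and 0 adjusted over the list alone) were shifted toward CLP, with S100a9 at 2.36 ± 0.41 and S100a8 at 2.22 ± 0.39. Acute phase genes together had adjusted p = 1.3e-27, and adjusted p = 0.00129 with an estimated correlation. Interferon-stimulated genes as a list had adjusted p = 9.28e-11, and adjusted p = 0.205 with an estimated correlation. Neutrophil markers as a list had adjusted p = 2.66e-09, and adjusted p = 0.216 with an estimated correlation. The neutrophil list mean was 9.56 in WT_pseudomonas and 9.82 in WT_CLP, the latter with WT_CLP 4 at 10.87. It was 9.79 in WT_saline and 9.28 in WT_sham, so much of this shift lies in the controls. Acute phase means were 9.88 in WT_pseudomonas and 10.46 in WT_CLP, and 9.53 in WT_saline and 9.05 in WT_sham. Platelet (0 of 11 were higher and 4 were lower, or 1 and 7 adjusted over the list alone) and T cell markers (1 of 18 was higher and 4 were lower, or 1 and 9 adjusted over the list alone) were shifted toward pneumonia, with Ppbp at -1.12 ± 0.22. Platelet markers together had adjusted p = 0.000179, and adjusted p = 0.162 with an estimated correlation. T cell markers by camera had adjusted p = 0.000292, and adjusted p = 0.33 with an estimated correlation. The pancreas list had a median of -1.31 (list adjusted p = 0.00676, and adjusted p = 0.601 with an estimated correlation) and 0 called members, and without the 5 arrays high in pancreas transcripts 111 of the 396 called genes (176 up, 220 down; limma) were still called.

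**Figure D5:**
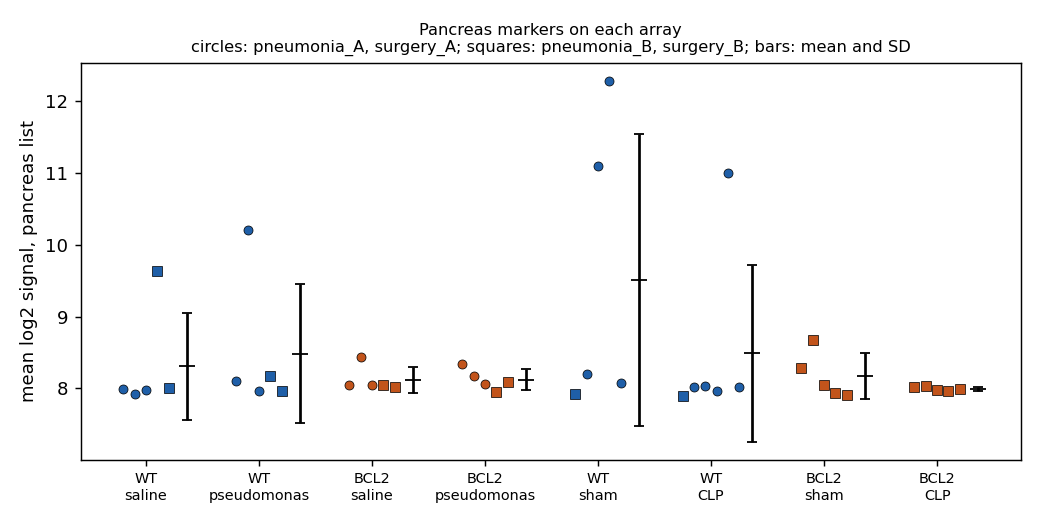
Mean log2 signal of 12 pancreas markers on each array by group, with group means and SD; 5 arrays, all from WT mice, lie between 9.63 and 12.29. Circles are batches pneumonia_A and surgery_A, squares are pneumonia_B and surgery_B.

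In BCL2 mice Ms4a6d (2.62 ± 0.35, adjusted p = 2.61e-05), Fpr2 (2.05 ± 0.29), Lcn2 (2.04 ± 0.38), the acute phase protein Saa3 (1.94 ± 0.43), S100a9 (1.73 ± 0.42) and Igkv4-72 (1.73 ± 0.35) responded more positively to CLP, and Cxcl1 (-2.45 ± 0.49, adjusted p = 0.00198), Akap12 (-1.54 ± 0.35), Cxcl2 (-1.50 ± 0.31), Gem (-1.29 ± 0.24), Cirbp (-1.29 ± 0.22) and Cxcl10 (-1.27 ± 0.35) more negatively. The values of Cxcl2 and Gem are not exact, since their sham and saline arrays all lay at the floor. Heat shock and chaperone genes were shifted toward CLP (8 of 15 were higher and 0 were lower, or 9 and 0 adjusted over the list alone), with Hsp90b1 at 0.64 ± 0.18 and Pdia4 at 0.63 ± 0.12, as were neutrophil markers (4 of 17 were higher and 0 were lower, or 8 and 0 adjusted over the list alone), acute phase genes (8 of 21 were higher and 0 were lower, or 11 and 1 adjusted over the list alone) and plasma cell markers (2 of 7 were higher and 0 were lower, or 4 and 0 adjusted over the list alone). Heat shock genes by camera had adjusted p = 6.75e-07, and adjusted p = 0.0286 with an estimated correlation. Neutrophil markers together had adjusted p = 1.14e-06, and adjusted p = 0.346 with an estimated correlation. Acute phase genes by camera had adjusted p = 4.94e-06, and adjusted p = 0.28 with an estimated correlation. Plasma cell markers as a list had adjusted p = 0.00158, and adjusted p = 0.28 with an estimated correlation. Immediate-early genes were shifted toward pneumonia (0 of 19 were higher and 2 were lower). Immediate-early genes together had adjusted p = 0.000178, and adjusted p = 0.314 with an estimated correlation. The test called 567 genes (383 up, 184 down; limma, n = 5 in each group). The 2 responses came from different batches, so batch and infection are not separable beyond each response's own control.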

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

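The tests of Mycn mRNA, of the genes next to Mycn, of red cells, lymphocyte share and surgery batches for the erythroid and cell cycle lists, and of the CLP signature in pneumonia were chosen after the result was seen. Over 240 tests of single arrays against the rest of their group, 20 stood apart (8.33%), where chance gives about 1 in 20.

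The CLP response differed between the genotypes at 314 genes (179 without WT_sham 2 and 564 without WT_CLP 1 or WT_sham 1), and other groupings of the arrays gave at most 153. This argues against chance, but the groupings do not keep batch and say nothing about batch. Scored on the 1818 genes called in WT pneumonia, the CLP response was 0.837 ± 0.0998 in WT and 0.377 ± 0.0446 in BCL2 mice (ratio 0.450, permutation p = 0.00702, n = 21), but the WT pair of surgery_B alone scored 0.538 and the WT arrays of surgery_A 0.892. These 2 errors are standard errors from the spread of the array scores, with no limma fit and no batch term. For this score pancreas tissue is argued against, since without the 3 WT arrays that hold it the ratio was 0.438. The score's genes come from WT pneumonia, where the pancreas list did not pass, so the score may hardly read pancreas transcripts. The count of 314 genes fell to 81 without these arrays and to 45 to 162 without other trios of WT arrays, so it does not decide. A batch difference and genotype cannot be told apart: on an index where WT arrays of surgery_A define a high and BCL2 arrays a low response, over the genes called without the pair scored, the only WT pair of surgery_B lay at 0.377 (564 genes), below 20 held-out WT pairs of surgery_A (0.529 to 1.26; 199 to 757 genes) and above 25 BCL2 pairs (-0.0608 to 0.264; 299 to 518 genes), pairs that reuse 9 and 10 arrays. Whether BCL2 mice may respond less in general also stays open, since the CLP signature in pneumonia, without that confounding, gave a ratio of 0.882 with permutation p = 0.152.

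The Mycn probe set with the large genotype difference had group means of 440 to 503 on WT and 2657 to 4455 on BCL2 arrays. More mature Mycn mRNA is argued against: on another Mycn probe set the highest upper 95% bound of the 4 differences was 0.276 log2 units. A differing chromosome segment next to Mycn stays open: the next measured genes, Ddx1 and Tubb2a-ps2, differed by at most 0.461 at the 95% bound (Tubb2a-ps2 was called in CLP mice, at -0.28), but a segment can differ with no change in them. Sequence carried by the transgene or its vector could be the source, and the test leaves it open: within BCL2 groups the signal correlated with Bcl2 at r = 0.165 (permutation p = 0.542, rho = 0.0481 with p = 0.859, 20 arrays; -0.0905 without the 2 farthest).

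The erythroid and cell cycle lists were higher in BCL2 mice in all 4 genotype contrasts at the preset correlation, and all 8 calls were lost with an estimated one (adjusted p 0.0989 to 0.395). With the erythroid list mean as covariate, which nearly follows genotype, the cell cycle list turned lower in BCL2 mice in sham (camera adjusted p = 1.43e-07) and CLP mice (camera adjusted p = 0.000298). Red cells left in the tissue lack cell cycle transcripts, whose median difference was at least 0.858 in the pneumonia model, and are argued against for that list only; for the erythroid list they stay open, since 4 adult globin probe sets rose by at most 0.296 at the 95% bound but lie near the top of the scale (group means 13.71 to 14.87, highest value 14.92). A lower share of lymphocytes that raises all other cell types alike is argued against, since the neutrophil, stromal and dendritic lists had medians of -0.102 or lower in saline and Pseudomonas mice, with 38 lower member calls. The surgery batches hold no pneumonia-model arrays, so the test in that model could not decide on them. It shows only that the difference is also present without them: within each pneumonia batch the medians in saline mice were 0.783 or higher. For sham and CLP mice a contribution of batch stays open. A higher share of dividing erythroid precursors in BCL2 spleens may be the source and was not tested apart from red cells for the erythroid list; a genotype effect and differences between the mouse colonies were not tested apart.

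Other groupings of the same arrays (100 per contrast, the real one included) gave the following highest counts. For pneumonia in WT mice the real count was 1818 and the highest other 835, in BCL2 mice 1581 and 567; for CLP in BCL2 mice 907 and 245; for BCL2 against WT in saline mice 1096 and 382, in sham mice 1055 and 793, after CLP 1241 and 421; for CLP against pneumonia in WT mice 460 and 57. In each of these 1 of 100 groupings, the real one, was as large, and chance can be excluded. In sham and CLP mice genotype nearly follows batch and the groupings do not keep batch, so there they say nothing about batch. Chance is also argued against for CLP in WT mice, 2736 against 2363. There the highest other grouping put 10 of 11 arrays in the opposite group and so nearly mirrors the real one. For Pseudomonas mice 2 of 100 groupings were as large, with 1614 against 1852; the other exchanged BCL2_pseudomonas 1 and 2 with WT_pseudomonas 3 and 5. That grouping sets 5 arrays with 18.6 to 20.5% of probe sets at the floor and medians of 310 to 324 against 5 with 17.5 to 18.0% and 331 to 339, and it called more genes than genotype did. Median centring gave 1366 genes for genotype, 1249 of them among the 1614. For CLP against pneumonia in BCL2 mice 2 of 100 were as large, 512 against 589, and the other put 18 of 20 arrays in the opposite group. The 2 comparisons of CLP with pneumonia were regrouped after each array was set against its own control, which gave 460 and 512 where the reported fit gave 396 and 567. For the difference between the genotypes' pneumonia responses 2 of 100 were as large, 3 against 3. A second way of regrouping, added after the first was seen and with the genotype difference taken out before, gave 0 against 85 there and 314 against 149 for CLP; so for the 3 genes of the pneumonia test the 2 ways differ, and chance is not taken as excluded.

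The differences between groups listed here are the 3 genes of the genotype difference in pneumonia response, the 314 of that in CLP response, and the 396 (WT) and 567 (BCL2) genes that differ between CLP and pneumonia.

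Arrays that stood apart from the rest of their group were these. WT_CLP 1 had 21.7% of probe sets at the floor (others 19.8 to 20.3), a mean correlation with its group of 0.948 (others 0.967 to 0.976) and an adipose list mean of 9.03 (others 9.63 to 9.89). BCL2_pseudomonas 3 had a mean correlation of 0.956 (others 0.970 to 0.973). The Mycn probe set read 671 on WT_saline 4 (others 438 to 473), which also had a dendritic list mean of 9.73 (others 9.58 to 9.62). Acute phase genes averaged 9.73 on WT_saline 2 (others 9.46 to 9.49), and anti-apoptotic genes 10.22 on BCL2_pseudomonas 4 (others 10.08 to 10.12). WT_pseudomonas 3 was high in NF-kB targets at 10.41 (others 10.32 to 10.33), heat shock genes at 10.77 (others 10.62 to 10.64) and oxidative phosphorylation at 11.01 (others 10.82 to 10.87). WT_sham 1 was high in glucocorticoid-responsive genes at 9.61 (others 9.05 to 9.19) and immediate-early genes at 9.73 (others 9.52 to 9.57). NK markers averaged 8.46 on BCL2_sham 5 (others 8.58 to 8.63) and plasma cell markers 10.21 on BCL2_sham 1 (others 9.97 to 10.04). Stromal markers averaged 9.72 on WT_pseudomonas 2 (others 9.83 to 9.85).

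Pancreas markers stood apart on WT_saline 4 at 9.63 (others 7.93 to 8.00), WT_pseudomonas 2 at 10.21 (others 7.97 to 8.17), BCL2_saline 2 at 8.43 (others 8.03 to 8.05) and WT_CLP 5 at 10.998 (others 7.90 to 8.04). WT_CLP 1 and WT_sham 1, named above, are the WT arrays of surgery_B.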

How the results depend on the processing

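Leaving out or adjusting for arrays with pancreas transcripts, adjusting for the erythroid list, leaving out the WT arrays of surgery_B and leaving out single WT arrays for the neutrophil list were chosen after the result was seen. The direction of nearly all named genes held: of 14161 results over 885 gene and contrast pairs, 12531 kept their direction and their side of the threshold, 1622 kept their direction without passing it, 5 uncalled values changed sign, and 3 called ones reversed. The 3 are Ighm in Pseudomonas mice under quantile normalization (-0.030), and Ptx3 (-0.11) and Dnaja1 (0.083) in sham mice with no batch term. List results, 300 per setting, were unchanged in side and direction in 199 with an estimated correlation (101 lost), 226 with fry (44 lost, 30 gained), 284 with no batch term, 288 with quantile normalization, 287 with no filter, 281 without the pancreas arrays and 293 with the pancreas covariate. Without each of the 11 WT surgery arrays, the neutrophil list after CLP in WT mice lost its call only without WT_CLP 4 (adjusted p = 0.0977). With the erythroid covariate 66 of 96 were unchanged, 12 lost and 16 gained. The cell cycle list reversed to lower in BCL2 mice, at adjusted p = 0.000298 after CLP and 1.43e-07 in sham mice, where that covariate nearly follows genotype.

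Counts of called genes moved by over 1.5 times as follows; unless said otherwise, the cause was not tested. Every probe set tested on its own, which tests more features, gave 3162 and 2689 for pneumonia (WT, BCL2), 4505 and 1437 for CLP, 505 and 0 for the genotype difference in CLP and pneumonia response, 1772, 2610, 1736 and 2009 for BCL2 against WT in saline, Pseudomonas, sham and CLP mice, and 627 and 991 for CLP against pneumonia (WT, BCL2). Single batches hold fewer arrays. Pneumonia_A alone gave 1037 and 935 for pneumonia, 1 for its genotype difference, and 512 and 422 for BCL2 against WT in saline and Pseudomonas mice; pneumonia_B gave 260, 124, 0, 3 and 3. Surgery_B alone gave 13 for CLP in WT mice, 0 for the genotype difference in CLP response (the spread of the single WT arrays is assumed to be that of the other groups), 15 for sham and 233 for CLP mice. Array weights gave 2578 for pneumonia in BCL2 mice, 10 and 545 for the genotype differences in pneumonia and CLP response, 1919 and 2542 for saline and Pseudomonas mice, and 1040 for CLP against pneumonia in BCL2 mice. With no batch term the counts were 0 and 114 for the genotype differences in pneumonia and CLP response, 4081 for BCL2 against WT after CLP, and 260 and 343 for CLP against pneumonia. A random batch block gave 636 in sham mice. Fits of only the groups compared gave 880, 8 and 775 in Pseudomonas, sham and CLP mice. The replicate block gave 0 and 65 for the genotype differences and 684 and 895 in saline and Pseudomonas mice. Without the 3 starred arrays the genotype difference in CLP response gave 51 and CLP against pneumonia in WT mice 238; without the 5 arrays with pancreas transcripts these gave 81 and 111. Leaving out other trios of WT arrays gave 45 to 162 for the former. Without the WT arrays of surgery_B it gave 564. With the erythroid covariate, which nearly follows genotype, the counts were 16, 33, 13 and 18 in saline, Pseudomonas, sham and CLP mice. The genotype difference in pneumonia response (3; limma, 260 at an unadjusted p under 0.05) also gave 0 with 1 fit over all arrays, plain eBayes, median centring, a floor at the 5th percentile or a filter at the 60th, 1 with no filter, 1 with the pancreas covariate and 5 with quantile normalization. Where limma gave 0 for it, 102 (pneumonia_B alone) to 412 (every probe set) had an unadjusted p under 0.05, and 322 did for the CLP difference in surgery_B alone.

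Leaving out 1 array in turn gave 1528 to 1884 and 1305 to 1686 for pneumonia (WT, BCL2), 2410 to 2764 and 544 to 899 for CLP, 0 to 4 and 179 to 564 for the genotype differences in pneumonia and CLP response, 796 to 1159, 1043 to 1915, 486 to 1459 and 309 to 1295 in saline, Pseudomonas, sham and CLP mice, and 287 to 533 and 433 to 658 for CLP against pneumonia. Single arrays that moved a count by over 1.5 times were BCL2_pseudomonas 5 (1043 in Pseudomonas mice), BCL2_CLP 3 (544 for CLP in BCL2 mice), WT_CLP 1 (309 in CLP mice), and BCL2_sham 2, BCL2_sham 3 and WT_sham 1 (617, 610 and 486 in sham mice). For the genotype difference in CLP response they were WT_CLP 1 and WT_sham 1 (564 each), WT_CLP 5 (205), WT_CLP 6 (209), WT_sham 2 (179), WT_sham 3 (197) and BCL2_CLP 5 (203). For that in pneumonia response 14 of 20 arrays moved it. Signal over background limits the measurement of the 17.5 to 22.2% of probe sets at the floor.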

Other observations

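The test of the 2 lists within groups below was chosen after the result was seen. Within groups and batches, arrays with a higher erythroid list mean also had a higher cell cycle list mean: r = 0.939 and rho = 0.943 over 39 arrays (permutation p = 1e-05 for each, the smallest these permutations can give), and r = 0.953 without the 2 farthest arrays. Within the batches r was 0.919 (pneumonia_A, 12 arrays), 0.965 (pneumonia_B, 8), 0.958 (surgery_A, 9) and 0.985 (surgery_B, 10). In pneumonia_B the residuals of the 2 arrays of a group mirror each other and count as 1 value, also among the 39 arrays. Group means of the erythroid list ran from 9.36 ± 0.69 (SD) in WT_saline to 10.95 ± 0.46 in BCL2_sham, and those of the cell cycle list from 9.18 ± 0.26 in WT_saline to 10.24 ± 0.35 in BCL2_pseudomonas.

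Col4a1, a basement membrane collagen, rose in pneumonia by 0.69 ± 0.14 in WT and 0.77 ± 0.14 in BCL2 mice and after CLP by 1.20 ± 0.11 and 0.84 ± 0.12. After CLP in WT mice the endothelial cadherin Cdh5 rose (0.85 ± 0.08) and the VEGF receptor Kdr fell (-0.78 ± 0.10), and the platelet transcripts Clec1b (-0.93 ± 0.13) and Ppbp (-0.94 ± 0.16) fell while Thbs1 rose (1.20 ± 0.13). Prdm1 rose in all 4 responses (0.77 ± 0.08, 0.45 ± 0.08, 0.59 ± 0.14 and 0.82 ± 0.14, in the order given above).

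Whether the numbers in the sample titles pair arrays stays open. The residuals of BCL2 and WT arrays of 1 number correlated at -0.502 to 0.0946 in the 4 pairs of pneumonia_A. In pneumonia_B, where the 2 pairs of a treatment mirror each other and give 1 value, r was 0.446 for saline and -0.206 for Pseudomonas. Those of CLP and sham arrays of 1 number correlated above 0.1 in 5 of 8 pairs (median 0.12), and pairs of unlike numbers were not compared.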
